A study of Arabidopsis thaliana with 4 samples.

How the data were processed

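Chromatin immunoprecipitation with an antibody against HA was followed by Illumina sequencing in 2 samples of Arabidopsis seedlings that express HA-tagged SHL, and 2 input samples of the same line were sequenced without an antibody. The ChIP and input samples were grouped by their titles, which also number the replicates. Only the ChIP samples had a file of their own, and the input samples were not analysed here.

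Per the submitters' processing notes, Bowtie2 2.2.8, SAMtools 1.3 and MACS 1.4 were used with the TAIR10 build. Each deposited list belonged to 1 ChIP sample, so the authors called peaks per sample. The settings, the filters and the control given to the peak caller are not stated in the sources used here. The deposited score of each peak came from the authors' peak caller. By the convention of MACS 1.4 it is 10 times the negative log10 of the p-value, which the lists have no header to state. The lowest scores were 20.01 in replicate 1 and 20 in replicate 2. Scores under 50 made up 58.7% of the peaks in replicate 1 and 58.1% in replicate 2. A score of exactly 3100 was shared by 226 peaks in replicate 1 and 196 in replicate 2, so scores from 3100 upwards were not read as ranks of strength. Read depth and read mapping could not be examined from these lists, and how reads from repeated sequence were placed is not stated in the sources used here. Scores were therefore compared within a list only. Intervals on shares of peaks or genes cover counting error only.

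Peaks of both replicates on the 5 nuclear chromosomes were compared, and an overlap of at least 1 bp counted as shared. Overlapping peaks of both replicates were merged into common regions. A region was called low-scoring if every peak in it scored under 100, and high-scoring if the best peak of each replicate scored at least 100. The chance overlap came from 1000 circular rotations of the other list within each chromosome (two-sided permutation test, smallest p 0.002). Midpoints of common regions were placed in protein-coding bodies, within 1 kb of them, in pseudogenes, in non-coding RNA genes, outside any annotated gene and in gene-poor windows. Each share was compared with 1000 rotations of the regions, with Benjamini-Hochberg adjustment over the 6 classes. Gene-poor windows were the 20 of 121 windows of 1 Mb with under 50% of the median number of protein-coding genes, and all others were called chromosome arms. Chromosome ends were taken as the largest position in the gene table or the lists.

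Gene positions came from the RefSeq gene table of assembly TAIR10.1, which holds 27444 protein-coding genes and 4843 pseudogenes on these chromosomes. The lists use TAIR10. Whether positions in both are the same was tested only from the data: the share of midpoints in protein-coding bodies was highest with no shift, at 57.0%, and was 29.0% after a shift of -1500 bp and 29.8% after 1500 bp. No gene coordinate is printed. The table gives no strand, exon or sequence, and it has no class for transposable elements. Pseudogenes are the genes so labelled in the table, and whether genes of transposable elements are among them was not examined. Windows around transcription start sites, exon, intron and untranslated classes, transposable elements and sequence motifs had been planned and were not run. For the same reason the planned definition of a target gene, which included 1 kb upstream of the start, was replaced by the gene body alone. A region within overlapping genes counted for each of them.

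Before the data were examined, 10 gene lists with 226 genes and 13 families defined by symbol were fixed. All 226 genes were found by locus identifier, and 219 carried the listed symbol in the reference. The share of target genes in each list or family was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 23 and exact (Clopper-Pearson) 95% intervals. Because this test ignores gene length and the clustering of regions, 10000 rotations of the regions over the genome were run as an alternative (smallest two-sided p 0.0002). Median gene length was 1861 bp for target genes and 2089 bp for others. Genes were named by a rule fixed beforehand: FT, SOC1, FLC, SHL and EBS in any case, up to 4 targets per list with the highest value of the lower score percentile of the replicates, and the 10 common regions ranked highest in the same way, with ties by position. Other names are marked where they appear. The results of 1 family and 1 gene that the rule would name are not reported here.

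Settings fixed before the data were examined, as alternatives, were a reciprocal overlap of 50%, peaks scoring at least 100, the 1000 highest-scoring peaks, the intersection in place of the union, any overlap with the gene body, rotations, and each replicate alone. Those chosen afterwards were regions scoring under 100, chromosome arms alone, regions moved by a random 20 to 200 kb (all regions, and those on arms), bodies extended by 1 kb on both sides, the reciprocal overlap for the gene groups, and a screen of gene symbols.

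The calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9. The code was tested on simulated data. All 1200 simulated partner peaks were recovered. In 100 simulated runs over 27444 genes, a list with placed regions had p under 0.05 in 100% of runs and a list without them in 3%. The simulated list was larger than every fixed list and its other regions were random. These runs therefore do not give the power for the fixed lists. Rotations of random regions gave p under 0.05 in 1% of runs.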

Results

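SHORT LIFE (SHL) is a plant chromatin protein with a BAH and a PHD domain, modules that bind modified histone tails, and EBS is its close relative. Its binding sites were mapped by chromatin immunoprecipitation with sequencing (ChIP-seq) in whole Arabidopsis thaliana seedlings of the Col-0 accession. The plants were about 10 days old and grown with 16 h of light and 8 h of dark. They were ebs shl mutants and carried SHL fused to an HA epitope under the SHL promoter, so an antibody against HA recovered the tagged protein with its DNA. The design held 2 ChIP samples and 2 input samples of DNA that was not immunoprecipitated. Each ChIP sample had a list of peaks with a score per peak, while the input samples had no file of their own and entered no test. Nothing in the labels said that the replicates were separate cultures, so agreement between them may be technical.

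Replicate 1 listed 3678 peaks, of which 3668 lay on the nuclear chromosomes and covered 4.46 Mb. Replicate 2 listed 3494 peaks, of which 3487 were nuclear and covered 4.77 Mb. Median peak width was 1077.5 bp in replicate 1 and 1216 bp in replicate 2. Scores are the authors' own and were used only to rank or filter peaks within a list. They ran from 20.01 to 3217 with a median of 39.3 in replicate 1, and from 20 to 3220.3 with a median of 40.0 in replicate 2. Read depth is unknown from these lists. Overlapping peaks of both replicates merged into 2186 common regions, with a median width of 1571 bp. A protein-coding gene was called a target gene when the midpoint of a common region lay within its body, which gave 1257 of 27444 genes, or 4.58%. Coordinates are those of the TAIR10 build. The reference used here gave gene bodies without strand, exons or untranslated regions, so a region in a gene was not placed further.

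Genes of photosynthetic light capture stood out among the target genes. Of the 13 genes with a light-harvesting complex symbol (LHCA or LHCB), which encode chlorophyll-binding antenna proteins, 10 were targets (76.9%, exact 95% interval 46.2 to 94.96, Fisher's exact adjusted p = 2.28e-10). Antenna genes under other symbols in the reference were not in this family. The wider photosynthesis list, which shares most of these genes, had 10 targets among 23 members (43.5%, interval 23.2 to 65.5, Fisher's exact adjusted p = 2.99e-07). It also held antenna genes that were not targets, among them its LHCB1 genes, named after their values were seen. LHCA4 (AT3G47470) held a region at chromosome 3, 17492680 to 17495004, with scores of 177.7 in replicate 1 and 155.5 in replicate 2. The region in LHCB6 (AT1G15820), at chromosome 1, 5445842 to 5447963, scored 215 and 112.2. LHCB3 (AT5G54270) at chromosome 5, 22038267 to 22040369, scored 107 and 91.6, and LHCA1 (AT3G54890) at chromosome 3, 20339039 to 20341168, scored 83.6 and 65.0. RBCS1A, for a small subunit of Rubisco, was the only photosynthesis target outside the antenna genes; it was named after its values were seen.

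Seed maturation genes, most of them silent in seedlings, were also frequent targets, at 8 of 21 members (38.1%, exact 95% interval 18.1 to 61.6; Fisher's exact adjusted p = 1.73e-05). ABI3 (AT3G24650), a master regulator of seed maturation, held a region at chromosome 3, 8997704 to 9000237, with scores of 115.1 and 67.3. ABI4 (AT2G40220), a transcription factor of abscisic acid signalling, held one at chromosome 2, 16795538 to 16798468, with scores of 61.5 and 101.1. Genes for the cruciferin storage proteins were targets as well. CRU3 (AT4G28520) scored 50.6 and 30.2 at chromosome 4, 14087252 to 14090329. CRA1 (AT5G44120) scored 28.3 and 130 at chromosome 5, 17756233 to 17758793. With a reciprocal overlap of 50% required between the replicates' peaks, 3 members were targets and the list did not pass (Fisher's exact adjusted p = 0.112).

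Regulators of meristems and organ patterning gave 7 targets among 22 members (31.8%, exact 95% interval 13.9 to 54.9; Fisher's exact adjusted p = 0.000148). KNAT1 (AT4G08150), a homeobox gene of the shoot meristem, held a region at chromosome 4, 5148939 to 5151159, with scores of 43.9 and 62.2. WOX5 (AT3G11260), which maintains the root stem cell niche, scored 31.9 and 34.1 at chromosome 3, 3526657 to 3528633. WOX1 (AT3G18010) scored 44.0 and 29.8 at chromosome 3, 6162160 to 6163787. SHR (AT4G37650), a regulator of radial patterning in the root, scored 57.0 and 29.2 at chromosome 4, 17691821 to 17693651.

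Auxin genes gave 8 targets among 26 members (30.8%, exact 95% interval 14.3 to 51.8; Fisher's exact adjusted p = 8.13e-05), and 5 of them were YUC genes, whose products make auxin. YUC6 (AT5G25620) had the highest scores of the list, 782.7 and 656.6, at chromosome 5, 8934064 to 8936424. YUC2 (AT4G13260) scored 47.5 and 82.7 at chromosome 4, 7721359 to 7724286. IAA2 (AT3G23030), for an Aux/IAA repressor, scored 41.1 and 36.4 at chromosome 3, 8180379 to 8182343. The Aux/IAA family as a whole did not pass, with 3 of 24 genes (Fisher's exact adjusted p = 0.156).

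Among families defined by gene symbol, 12 of 67 WRKY transcription factor genes were targets (17.9%, exact 95% interval 9.61 to 29.2; Fisher's exact adjusted p = 0.000154). The ERF/DREB transcription factors had 7 targets among 33 genes (21.2%, interval 8.98 to 38.9; Fisher's exact adjusted p = 0.00179). Cytochrome P450 genes had 25 among 224 (11.2%, interval 7.35 to 16.0; Fisher's exact adjusted p = 0.000148). CYP79B2 and CYP79B3, which start indole glucosinolate synthesis, were among the P450 targets; they were picked after their values were seen. The P450 family did not pass with a reciprocal overlap of 50%, where 15 genes were targets (Fisher's exact adjusted p = 0.115).

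In all, 8 of the 23 lists and families passed Fisher's exact test, and the same 8 passed against 10000 rotations of the regions. Their target genes came mainly from regions of low score. Of 862 genes targeted only by regions whose peaks all scored under 100, 62 (7.19%) belonged to the 8 groups. Of 306 targeted only by regions whose best peak scored at least 100 in each replicate, 5 did (1.63%; two-sided Fisher's exact p = 0.000145). This comparison was chosen after the data were examined, and the groups had been selected on all regions together. With peaks of at least 100 alone, target genes numbered 308 and none of the 23 groups passed Fisher's exact test after adjustment, while 2 (photosynthesis and light-harvesting) had an unadjusted p under 0.05.

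**Figure D1:**
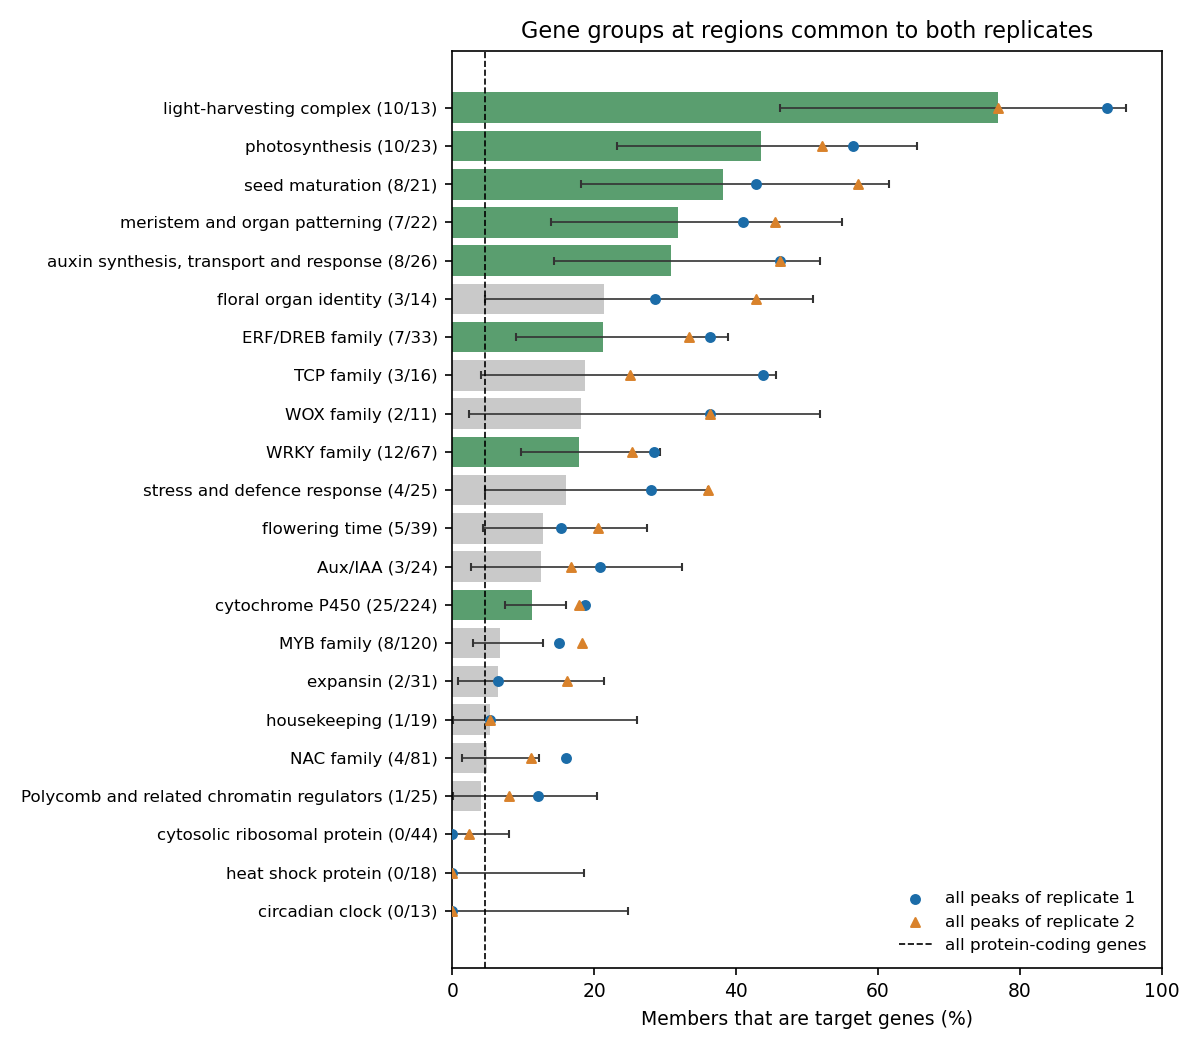
Share of the members of the fixed lists and families reported here that were target genes, in percent, with the count of targets and members beside each name. Bars are common regions of both replicates, whiskers are exact 95% intervals, green bars passed Fisher's exact test after adjustment, and the dashed line marks the 4.58% of all protein-coding genes. Circles and triangles show all peaks of replicate 1 and replicate 2 alone. The light-harvesting bar reaches 76.9%, and the circadian clock, heat shock and ribosomal protein groups are at 0.

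Flowering-time genes were of interest because loss of SHL or EBS alters flowering. Neither replicate listed a peak on FT (AT1G65480), the mobile flowering signal, or within 1 kb of it. SOC1 (AT2G45660), a floral integrator, was a target, with scores of 52.2 and 86.4 at chromosome 2, 18808916 to 18811465. The body of the floral repressor gene FLC (AT5G10140) held no common region. The edge, but not the midpoint, of a common region at chromosome 5, 3168988 to 3172614, lay within 1 kb of FLC; this region scored 2578 in replicate 1 and 1536 in replicate 2, and replicate 2 also had a peak of 27.2 on the body. TEM2 (AT1G68840) and TEM1 (AT1G25560), which encode repressors of FT, were both targets. TEM2 scored 114.4 and 107.6 at chromosome 1, 25880121 to 25881995. TEM1 scored 37.95 and 32.3 at chromosome 1, 8980918 to 8983340. AGL42 (AT5G62165) scored 24.3 and 52.6 at chromosome 5, 24964567 to 24966435. The last target of the list was LFY, named after its values were seen. With 5 of 39 members (12.8%, exact 95% interval 4.30 to 27.4), the flowering-time list did not pass (Fisher's exact adjusted p = 0.0658). It passed in replicate 2 alone, with 8 members (Fisher's exact adjusted p = 0.0187), but not in replicate 1 alone, with 6 (Fisher's exact adjusted p = 0.188). Against rotated regions the 5 targets in common regions did not pass (adjusted permutation p = 0.268).

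Floral organ identity genes had 3 targets among 14 members (21.4%, exact 95% interval 4.66 to 50.8; Fisher's exact adjusted p = 0.0591). These were SEP4 (AT2G03710) at chromosome 2, 1129144 to 1130801, FUL (AT5G60910) at chromosome 5, 24503728 to 24506532, and AP1 (AT1G69120) at chromosome 1, 25982455 to 25984042. SEP4 scored 33.5 and 47.5, FUL scored 25.8 and 50.9, and AP1 scored 22.6 and 31.4. The list passed in replicate 1 alone, with 4 targets (Fisher's exact adjusted p = 0.0421), and in replicate 2 alone, with 6 (Fisher's exact adjusted p = 0.000907). Against rotated regions the 3 targets in common regions did not pass (adjusted permutation p = 0.192). By Fisher's exact test the stress and defence list stood likewise, with 4 of 25 members in common regions (16%, interval 4.54 to 36.1, Fisher's exact adjusted p = 0.0591). In replicate 1 alone it had 7 (Fisher's exact adjusted p = 0.00866) and in replicate 2 alone 9 (Fisher's exact adjusted p = 0.000204), and it passed against rotated regions (adjusted permutation p = 0.023). Its targets were RAV1 (AT1G13260), with scores of 199.9 and 170.6 at chromosome 1, 4542059 to 4544385, ERF104 (AT5G61600), with 30.2 and 34.4 at chromosome 5, 24766182 to 24767597, and the pathogenesis-related genes PR5 and PR1. PR5 (AT1G75040) scored 29.0 and 42.7 at chromosome 1, 28177569 to 28179006, and PR1 (AT2G14610) scored 27.2 and 21.7 at chromosome 2, 6241542 to 6242677. Outside the body of PR5 but within 1 kb of it, a further peak scored 1333.5 in replicate 1 and 941.6 in replicate 2.

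Polycomb and related chromatin regulators had 1 target among 25 members (4%, exact 95% interval 0.101 to 20.4; Fisher's exact adjusted p = 1). It was EMF1 (AT5G11530), whose product acts in Polycomb silencing, with scores of 209.9 and 180.6 at chromosome 5, 3695410 to 3697882. The SHL gene itself (AT4G39100) was overlapped by a common region at chromosome 4, 18215297 to 18219266, with scores of 68.9 and 80.8, but the midpoint lay outside its body. The plants also carried the SHL transgene, and reads from it may have been placed here, which could not be examined. EBS (AT4G22140) had a peak of 25.7 in replicate 2 and none in replicate 1. None of the 13 circadian clock genes was a target, which allows a share of up to 24.7% (exact 95% interval; Fisher's exact adjusted p = 1). None was found among 44 ribosomal protein genes with an RPL or RPS symbol (upper limit 8.04%, Fisher's exact adjusted p = 0.386) or 18 heat shock protein genes (upper limit 18.5%, Fisher's exact adjusted p = 1). The RPL or RPS symbol does not set the cell compartment of a ribosomal protein. The housekeeping list had 1 target among 19, UBQ10 (AT4G05320), with scores of 76.0 and 64.0 at chromosome 4, 2718784 to 2720991 (Fisher's exact adjusted p = 0.798). MYB (8 of 120; Fisher's exact adjusted p = 0.386), NAC (4 of 81; 0.954), TCP (3 of 16; 0.0658), WOX (2 of 11; 0.155) and expansin genes (2 of 31; 0.833) did not pass either. In single replicates some of them did. MYB passed in replicate 1 alone with 18 genes and in replicate 2 alone with 22 (Fisher's exact adjusted p = 0.037 and 0.000533), and WOX with 4 in each (Fisher's exact adjusted p = 0.0217 and 0.0161). TCP passed in replicate 1 alone with 7 genes (Fisher's exact adjusted p = 0.000451), and NAC with 13 (Fisher's exact adjusted p = 0.0421), but neither did in replicate 2. TCP also passed with any overlap of the gene body, at 4 genes (Fisher's exact adjusted p = 0.0392), and with low-scoring regions alone, at 3 (Fisher's exact adjusted p = 0.0295).

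The regions fell into classes of score that differed in where they lay. There were 1092 common regions whose peaks all scored under 100, 932 whose best peak scored at least 100 in each replicate, and 162 between them. Of the low-scoring regions, 78.5% had their midpoint in a protein-coding gene body, against a mean of 54.3% after 1000 circular rotations of the regions along their chromosomes (ratio 1.45, adjusted permutation p = 0.004). Of the high-scoring regions, 32.2% did, against 53.8% (ratio 0.598, adjusted permutation p = 0.004). Pseudogenes held 34.3% of the high-scoring midpoints, against 9.10% after rotation (ratio 3.78, adjusted permutation p = 0.004), and 8.43% of the low-scoring midpoints, against 8.79% (ratio 0.959, adjusted permutation p = 0.795). The gene table has no class for transposable elements, and whether their genes are among its pseudogenes was not examined. Against regions moved by 20 to 200 kb the high-scoring ratios were less extreme, at 1.69 for pseudogenes and 0.886 for protein-coding bodies (adjusted permutation p = 0.004 for both). The low-scoring pseudogene result depended on the comparison: against regions moved by 20 to 200 kb the ratio was 1.23 (adjusted permutation p = 0.024), and on the chromosome arms it was 0.441 against rotation (0.002) and 1.26 against moves (0.182). Gene-poor windows of 1 Mb, which lie mostly around the centromeres, held 45.2% of the high-scoring and 11.8% of the low-scoring regions. On the chromosome arms, 86.5% of the low-scoring midpoints were in protein-coding bodies, against 54.2% after rotation (adjusted permutation p = 0.002). Rotation also carries arm regions into gene-poor windows, so part of this excess is built in. Against arm regions moved by 20 to 200 kb the comparison was 86.5% with 63.0% (ratio 1.37, adjusted permutation p = 0.003). High-scoring midpoints on the arms did not differ from rotated ones, at 50.5% against 53.9% (ratio 0.937, adjusted permutation p = 0.279). Against arm regions moved by 20 to 200 kb they were lower, at 50.5% against 57.3% (ratio 0.881, adjusted permutation p = 0.003). The moved regions and the split into arms were chosen after the data were examined.

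**Figure D2:**
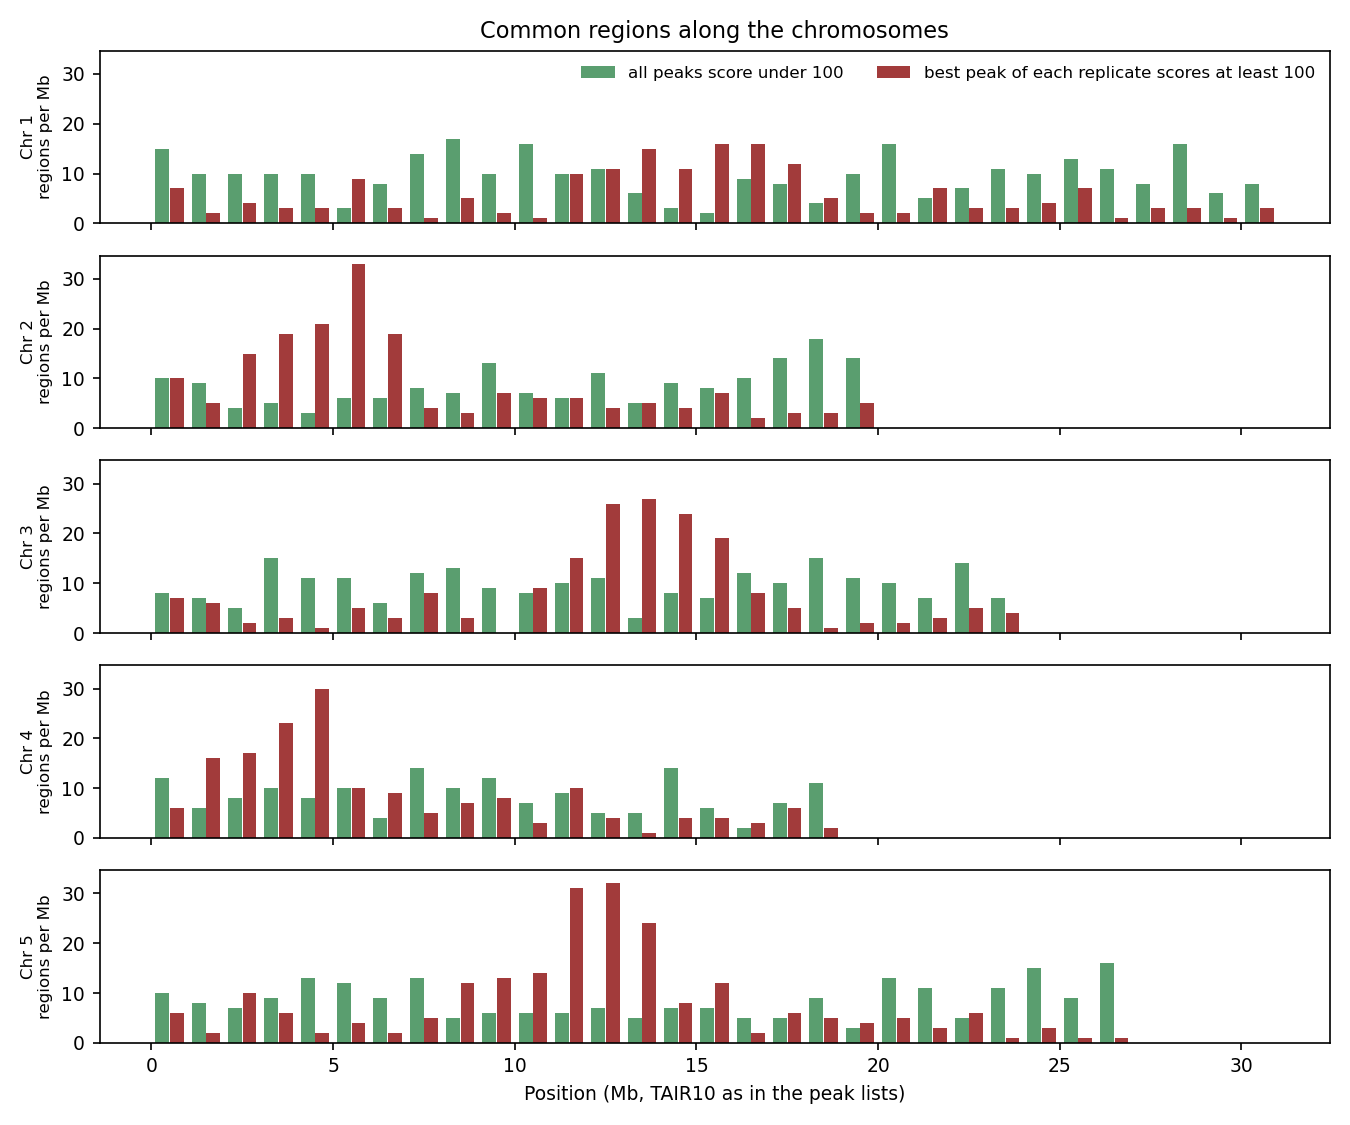
Number of common regions per Mb along the 5 nuclear chromosomes, by position in Mb. Green bars are regions whose peaks all scored under 100, and red bars are regions whose best peak scored at least 100 in each replicate. Red bars cluster in 1 part of each chromosome, and 45.2% of these regions lay in gene-poor windows, against 11.8% of the regions in green.

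**Figure D3:**
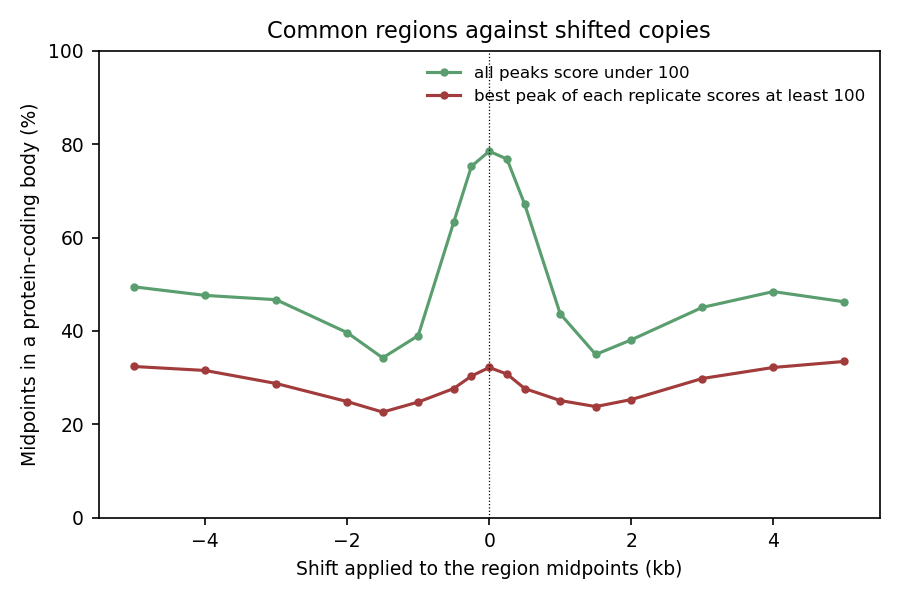
Percent of region midpoints inside a protein-coding gene body after all midpoints were shifted by the distance on the x axis, in kb. The low-scoring regions (green) stand at 78.5% with no shift and at 34.3% after a shift of -1500 bp. The high-scoring regions (red) stand at 32.2% with no shift.

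Over all 2186 common regions, 57.0% of midpoints were in protein-coding bodies, which did not differ from rotated regions (54.0%; ratio 1.06, adjusted permutation p = 0.105). The call depended on the setting. An excess was called in each replicate alone, with ratios of 1.198 in replicate 1 and 1.176 in replicate 2 (adjusted permutation p = 0.003 for each). It was also called against regions moved by 20 to 200 kb (ratio 1.202) and on the chromosome arms alone (ratio 1.37, adjusted permutation p = 0.003 for both). Rotation carries arm regions into gene-poor windows, so the ratios to rotation on arms are in part built in. Midpoints outside but within 1 kb of a protein-coding gene made up 10.6%, against 20.4% after rotation (adjusted permutation p = 0.003). Sequence without any annotated gene held 21.2%, against 35.9% (adjusted permutation p = 0.003). Pseudogenes held 20.6%, against 8.90%, and gene-poor windows 27.5%, against 17.0% (adjusted permutation p = 0.003 for both). On the chromosome arms alone the pseudogene share did not differ, at 9.09% against 8.73% (ratio 1.04, adjusted permutation p = 0.807), while over all regions it exceeded that of regions moved by 20 to 200 kb (13.2%; adjusted permutation p = 0.003). Non-coding RNA genes held 2.38%, against 2.19% (adjusted permutation p = 0.557).

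The 10 common regions that the naming rule took by score were outside the genes named above. A score of exactly 3100 recurred in both lists, in 192 common regions in both replicates, so scores from 3100 upwards do not rank these regions by strength. A region over the pseudogene AT1G51175 at chromosome 1, 18969229 to 18973181, had scores of 3173 and 3175. Another covered the pseudogene AT3G33115 in a gene-poor window at chromosome 3, 13883145 to 13887095, with scores of 3179 and 3100. The others scored exactly 3100 in both replicates and were taken by position, so all were on chromosome 1. Protein-coding genes held 5 of the 10: GAE2 (345360 to 347313), the metacaspase gene MC1 (411048 to 412770), STN1 (2187294 to 2189115), AT1G11850 (3998352 to 4000596) and ATLP-1 (6276122 to 6278586). The pseudogenes AT1G05135 (1477065 to 1480317) and AT1G20390 (7065221 to 7076558) held a region each, and the region at 237579 to 239457 held no annotated gene.

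The lists of the replicates overlapped well beyond chance. In replicate 1, 2284 of 3668 nuclear peaks overlapped a peak of replicate 2 (62.3%, Wilson 95% interval 60.7 to 63.8), against a mean of 7.30% when the other list was rotated. In replicate 2, 2248 of 3487 did (64.5%, interval 62.9 to 66.0), against 7.61%. Both comparisons gave a two-sided permutation p of 0.002, the smallest that 1000 rotations allow. Repeatability followed the score. Of the peaks scoring 20 to 30, 31.6% in replicate 1 and 32.5% in replicate 2 were shared, and from 300 upwards all were. Peaks of at least 100 made up 29.0% of each list, and the gene groups rest on peaks with a partner only. Across common regions, which are not independent replicates, the Spearman correlation of the scores was 0.888. It was 0.324 among the low-scoring regions, whose scores span only 20 to 100, and 0.971 among the high-scoring ones, 192 of which were tied at 3100, so these 2 values are not compared.

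**Figure D4:**
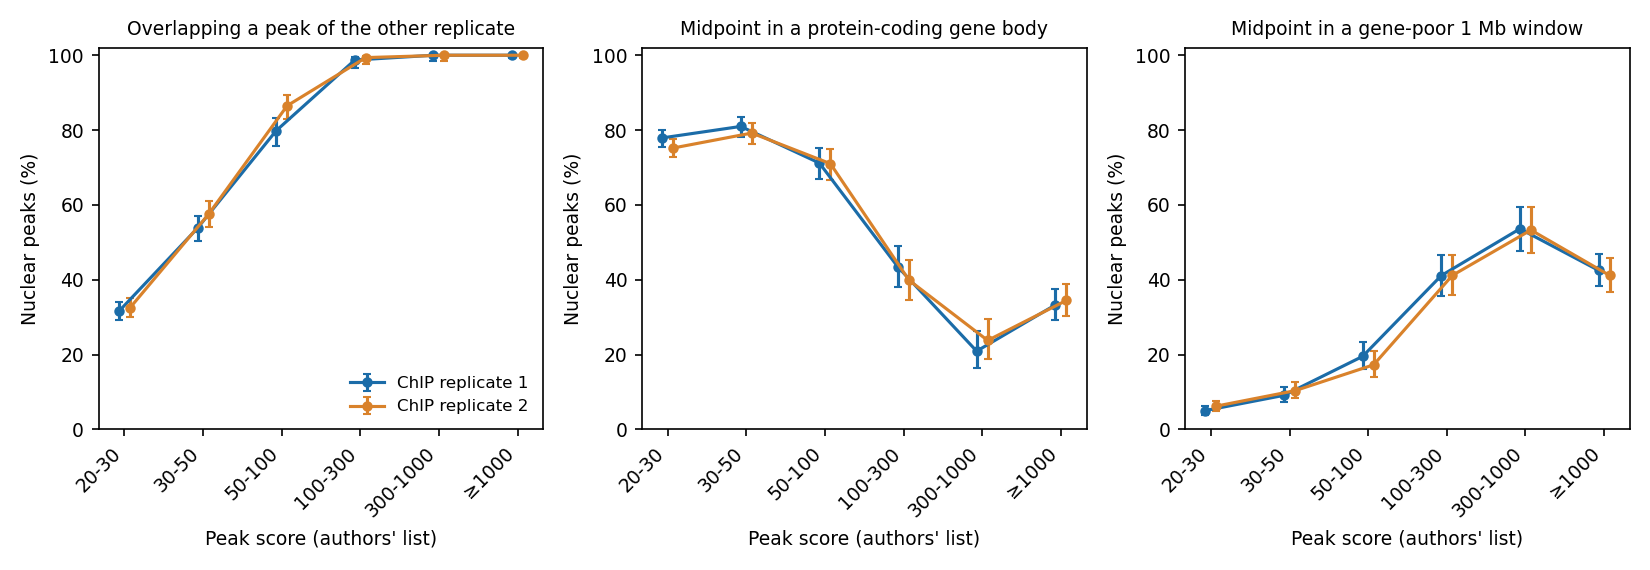
Percent of nuclear peaks that overlapped a peak of the other replicate (left), had their midpoint in a protein-coding gene body (middle) or lay in a gene-poor window of 1 Mb (right), by class of the authors' score. Points are the lists of replicate 1 (blue) and replicate 2 (orange), with Wilson 95% intervals. Sharing climbs from 31.6% and 32.5% in the lowest class to 100% in the upper classes, while the share in protein-coding bodies starts at 77.9% and 75.2% and falls to 20.9% and 23.8% for scores of 300 to 1000. From 1000 upwards that share is higher again, at 33.3% and 34.45%.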

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

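Rotations of the regions for the gene lists were fixed before the data were examined, and the other tests of explanations in this part were chosen after the results they bear on had been seen. Peaks on the mitochondrial genome were outside every comparison above. Replicate 1 listed 10 of them and replicate 2 listed 7, and no chloroplast peak was in either list. They formed 7 common regions, the highest at 188438 to 192921 of the mitochondrial genome with a score of 3100 in both replicates. A score of at least 100 was reached by 8 of 10 mitochondrial peaks in replicate 1 (80%), against 28.9% of nuclear peaks (two-sided Fisher's exact p = 0.00123). In replicate 2 it was reached by 5 of 7 (71.4%), against 28.9% (two-sided Fisher's exact p = 0.0246).

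The high-scoring regions were the most repeatable signal, and they were less often in protein-coding bodies (32.2%) and more often in pseudogenes (34.3%) than rotated regions. On arms the share in protein-coding bodies did not differ from rotation (ratio 0.937, adjusted permutation p = 0.279) and the share in pseudogenes did (ratio 2.08, adjusted permutation p = 0.006), but rotation also carries regions into gene-poor windows; against arm regions moved by 20 to 200 kb the ratios were 0.881 for protein-coding bodies and 2.998 for pseudogenes (adjusted permutation p = 0.003 for both), which argues against location as the whole cause. A candidate explanation is signal that does not come from chromatin binding. Mitochondrial DNA carries no nucleosomes, yet 80% of the peaks placed on it in replicate 1 scored at least 100. This cannot decide the question. It rests on 10 peaks in replicate 1 and 7 in replicate 2. How reads from repeated sequence were placed is not stated, so these peaks need not come from mitochondrial DNA. Binding of SHL to pseudogene-rich chromatin remains open, since pseudogenes held 1.69 times as many high-scoring midpoints as regions moved by 20 to 200 kb (permutation p = 0.002). An untagged control would tell such binding from signal without it, but none was among the samples. Misplaced reads from repeats were not tested.

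Antenna genes are among the most highly expressed genes of green seedlings, so the photosynthesis list was compared with housekeeping and ribosomal protein genes. Housekeeping genes and ribosomal protein genes with an RPL or RPS symbol, pooled, had 1 target among 63, against 10 among 23 photosynthesis genes (Fisher's exact p = 3.00e-06). The pattern was therefore not shared by these groups. Their expression was not measured, so the comparison cannot decide whether signal at highly expressed genes plays a part. Gene length or clustering of regions is argued against, since the central 95% of rotations ended at 3 photosynthesis targets, against 10 observed. The class of high-scoring regions is not needed, because the list passed with low-scoring regions alone (5 targets, Fisher's exact adjusted p = 0.00211). Light-driven transcription of these genes, or binding of SHL to them, may account for the pattern, and neither was tested. No expression data of these plants were used, and no untagged control was among the samples.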

How the results depend on the processing

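Overlap of the lists was far above rotation under every setting tried. No paired analysis was possible because the ChIP and input samples share numbers 1 and 2 in the labels but the input samples have no file of their own. Strand-dependent alternatives (start site inside the region, 500 bp start-site window) and motifs were not run. Read depth is unknown, so its limits could not be set.

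With peaks scoring at least 100, common regions numbered 932, target genes 308, and groups that passed 0. The body ratio turned to 0.600; the cause was not tested. Target counts were then 0 in seed maturation, meristem, WRKY, P450, floral organ, housekeeping, MYB, NAC, TCP, WOX and Aux/IAA, 1 in auxin, and 2 each in photosynthesis, light-harvesting and ERF/DREB. Fewer target genes were tested in that setting. Of 29 named targets 6 were kept.

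With each replicate alone, which lists more peaks, target genes ranged from 2185 to 2320 and groups that passed from 13 to 14. The body ratio ranged from 1.176 to 1.198, flowering-time targets from 6 to 8, floral organ targets from 4 to 6, and stress targets from 7 to 9. All 29 named targets were kept.

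A reciprocal overlap of 50% left 3 seed maturation and 15 P450 targets, and neither group passed; the cause was not tested. It lost FUL, ABI4 and CRA1. Rotations passed the stress list, with 4 targets (adjusted permutation p = 0.023).

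The settings chosen after seeing the data raised the body ratio past the threshold: 1.202 with moves of 20 to 200 kb, 1.45 in regions under 100 and 1.37 on chromosome arms. In regions under 100 the ratio was 0.959 for pseudogenes, no longer past the threshold (adjusted permutation p = 0.795) but 1.23 with moves of 20 to 200 kb (0.024) and 0.441 on arms (0.002), and 0.703 for gene-poor windows, the reverse of all regions together (adjusted permutation p = 0.006), and the 3 floral organ targets passed (Fisher's exact adjusted p = 0.0223). On arms the pseudogene ratio was 1.04, no longer past the threshold (adjusted permutation p = 0.807). Rotation carries arm regions into gene-poor windows, so the ratios to rotation on arms are in part built in.

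Some groups that passed under neither setting turned from above to below the share of other genes, or the reverse; the cause was not tested. Polycomb targets (1, below) were above with 2 to 3 in single replicates, 2 with any overlap, 2 with bodies extended by 1 kb, and 1 each with scores of at least 100 and reciprocal overlap. Clock targets (0) were 1, above, with any overlap or extended bodies. Housekeeping (1, above) was below with 1 in each replicate alone, with any overlap and with extended bodies, as was NAC (4) with 4 in the last 2. Expansin (2, above) was below with 2 in replicate 1 alone (5 in replicate 2) and with extended bodies, 1 with reciprocal overlap and 0 in regions under 100.

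For overlap, position, the fixed lists and the families that passed, 113 tested values kept their direction and side of the threshold. Another 21 turned direction, whether or not the call changed. Of those that kept their direction, 12 newly passed and 7 no longer passed. Some of the 21 also lost their call: seed maturation, meristem, WRKY and P450 with scores of at least 100, and pseudogenes in regions under 100. The body ratio with scores of at least 100 turned direction and newly passed. Of the untested counts 12 stayed within 1.5 times the main count and 7 did not.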

Other observations

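All tests in this part were chosen after the data had been seen. When 225 symbol stems with at least 8 members were screened, 15 passed Fisher's exact test after adjustment. The stems LHCB, CYP, WRKY and ERF among them repeat genes of families reported above, so not all 15 are further groups. Arabinogalactan protein genes (AGP), which encode cell wall proteoglycans, had 11 targets among 30 (Fisher's exact adjusted p = 9.80e-06). LSH genes, regulators of organ boundaries, had 5 among 10 (Fisher's exact adjusted p = 0.00176), and UGT glycosyltransferase genes had 11 among 58 (Fisher's exact adjusted p = 0.0018). YUC genes, the same 5 as in the auxin list, were 5 targets among 11 (Fisher's exact adjusted p = 0.00206), the cytokinin synthesis genes IPT had 4 among 9 (Fisher's exact adjusted p = 0.0086), and the abscisic acid receptor genes PYL had 4 among 11 (Fisher's exact adjusted p = 0.0167). The IDD zinc finger genes, the GPAT genes of cutin and suberin synthesis and the Argonaute genes (AGO) each had 4 among 9 (Fisher's exact adjusted p = 0.0086).

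A group of another kind was the GRP genes, many of which encode glycine-rich proteins. It had 7 targets among 15 (Fisher's exact adjusted p = 0.000145), of which 6 came from high-scoring regions (Fisher's exact adjusted p = 1.97e-06) and 0 from low-scoring ones. CAT genes, a stem shared by a catalase and amino acid transporters, had 4 targets among 11, 3 of them from high-scoring regions (Fisher's exact adjusted p = 0.0243). With low-scoring regions alone 9 stems passed, and with high-scoring regions alone 3 did. AGP passed with either class, with 6 targets from low-scoring regions (Fisher's exact adjusted p = 0.00744) and 4 from high-scoring ones (Fisher's exact adjusted p = 0.0254).

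Peaks without a partner in the other replicate numbered 1384 in replicate 1, with a median score of 26.4, and 1239 in replicate 2, with a median of 26. In replicate 1, 77.2% had their midpoint in a protein-coding body, against 59.97% after moves of 20 to 200 kb, and in replicate 2 75.6% did, against 60.8% (permutation p = 0.002 for both, the smallest possible). A hypothesis is that peaks listed in 1 replicate hold binding that fell below the threshold of the other list. Among 1852 genes hit in 1 replicate only, 6 of the 8 groups passed again, all but photosynthesis (Fisher's exact adjusted p = 0.0539) and light-harvesting, with 2 members left to test (Fisher's exact adjusted p = 0.213). Of the 15 groups that had not passed in common regions 6 passed here as well, MYB with the lowest value of all (Fisher's exact adjusted p = 2.64e-05), so passing was not particular to the 8. Counts for each replicate alone had been seen before this test and in part imply it, and a preference of the assay for the same kinds of gene in both samples would give this too and was not tested.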
